A study of Mus musculus with 8 samples.

How the data were processed

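Single-cell RNA was measured in P14 cells, CD8 T cells with a transgenic receptor for an LCMV epitope, sorted as CD8+CD90.1+ from mouse spleen at day 30 after LCMV infection. The labels name 4 groups of 2 libraries each: a Rosa KO control edit, Dnmt3a KO, Tet2 KO and Asxl1 KO. The strain of the virus, the positions of the guides and the number of animals behind each library are not in the labels. Each of the 8 libraries was made with the 10x Genomics 3' v3.1 chemistry, per the labels. Per the submitters' processing notes, reads were counted with Cell Ranger 6.0.0 against mm10. The deposited matrices hold counts, that is raw UMI counts per gene and cell barcode, without normalization, and the smallest barcode total of a library was 500 or 501 UMIs.

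The matrices share 32285 genes. Of their gene IDs, 32158 were found in GENCODE vM21, and 38 symbols belonged to more than 1 ID, so genes were kept apart by ID. Cells were kept with at least 500 detected genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Scrublet, run per library in scanpy 1.11.5, marked between 0 and 11 barcodes of a library, at most 0.502% of the cells that passed the filters, which is too few for it to have worked on libraries of this size. The remaining cells were normalized to a common total, log-transformed, reduced to 2000 variable genes and 30 principal components, and clustered with 15 neighbours and Leiden resolution 1 (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python 3.11.15). Clusters were named by the highest score among 6 sets of state markers and 11 lists for other cell types of the spleen. All names are "-like" labels from RNA. Clusters named B cell, plasma cell, monocyte or macrophage, neutrophil, dendritic cell or CD4 T cell, and a few droplets with little CD3 RNA, were left out of the P14-like sums and used only as reference cells.

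For each library, UMI counts of its P14-like cells were summed (pseudobulk), so that libraries and not cells were the replicates. The sums were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, and the quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05, with all 8 libraries in 1 fit. There were 11970 genes tested. The biological coefficient of variation was 0.0485, with 11.3 prior degrees of freedom. The sums held between 8207580 UMIs (Tet2 KO replicate 2) and 15973627 UMIs (Asxl1 KO replicate 2), and the median P14-like cell held between 2374 UMIs (Asxl1 KO replicate 2) and 5453.5 UMIs (Rosa KO replicate 1). On data simulated at this depth and spread, in which 50 genes at each fold were changed among 11970, the test recovered 98%, 94% and 96% of 4-fold changes, 78%, 80% and 76% of 2-fold changes, 62%, 62% and 56% of 1.5-fold changes and 32%, 20% and 26% of 1.25-fold changes in the Dnmt3a, Tet2 and Asxl1 KO comparisons, and 10%, 8.57% and 6.62% of its calls were false. DESeq2 1.42.0 on the same simulated data recovered 94%, 86% and 84% of 4-fold changes with 2.52%, 1.77% and 1.85% false calls.

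Fixed lists of genes, 29 for states and pathways and 11 for other cell types, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with p-values adjusted over 114 tests. The HOX and stromal lists had 2 tested members each and were not tested. Shares of cells were compared by an exact permutation test over the 2520 assignments of 8 libraries to 4 groups, for which the smallest possible p is 0.00952. A pair of 2-library groups alone cannot reach the threshold. Shares of cells with a UMI were taken after every cell was thinned to 2000 UMIs. Changes within a class were tested the same way on sums of that class, in the 5 classes with at least 20 cells in every library. The recently activated-like class was left out there because Asxl1 KO replicate 2 had 15 such cells. A difference between the change in progenitor-like cells and that in the other P14-like cells was tested as an interaction with library as a block.

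Genes named in the report follow a fixed rule. They are the targeted gene, the 8 genes with the highest and the 8 with the lowest log2 fold change among called genes with an average log2 CPM of at least 4 and both knockout libraries on the same side of both controls, and 28 key genes of T cell states, of which 27 are given. A few genes that the rule names are not reported here, though they stay in the fits, lists and counts. Receptor segments, immunoglobulin and haemoglobin genes, markers of other cell types alone and provisionally named gene models were not eligible. Within a class the rule takes 4 and 4, and a list is shown by up to 4 members with the smallest adjusted p. These rules, the lists, the groups, the tests and most alternatives were set before the data were examined.

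Alternatives were DESeq2's size factors in edgeR, the DESeq2 Wald test, no filter on low counts, only the 4 libraries compared, a block for the replicate number, each library left out in turn, a stricter cell filter (1000 genes, 5% mitochondrial UMIs), doublets kept, clusters of other cell types kept, proliferating-like cells left out, and sums of equal size (1301 cells per library, 2374 UMIs per cell). For lists they were an estimated correlation, fry and a prior count of 0.5. For classes they were Leiden resolution 0.5 and 1.5, clustering without the 5641 called genes, classes carried over from Rosa KO cells, and a test on numbers of cells. For UMI shares they were no thinning and thinning to 1500 and to 3000 UMIs. Chosen after the data had been seen were sums of activation-low cells (at most 0.288% of UMIs in the activation-induced list, the 75th percentile of Dnmt3a KO cells), removal of the 6% of cells with the highest Scrublet scores, and clustering without activation genes. Of the activation genes, 31 were picked by a correlation above 0.15 with the recently activated markers in Rosa KO cells. The lists in activation-low cells, in sums of equal size and in host cells, the share of cells with both Tcf7 and Slamf6, and Cd4 as a named gene were added at the same time.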

Results

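Genes mutated in clonal blood expansions, among them Dnmt3a, Tet2 and Asxl1, encode enzymes and cofactors that write or remove marks on DNA and chromatin. The question here is what losing each of them does to virus-specific CD8 T cells late in infection. In all 3 knockouts, RNA of the progenitor regulator Tcf7 and of its companions Slamf6 and Id3 was higher than in Rosa KO cells, and RNA of the effector genes Cx3cr1, Zeb2, Klrg1 and Gzma was lower. The knockouts differed in the rest. Tet2 KO cells had the most RNA of the cell division gene Mki67 among the knockouts, and less Tox. Asxl1 KO cells had the least granzyme RNA, and Dnmt3a KO cells kept the most RNA of Zeb2, S1pr5, Klrg1, Cx3cr1 and Gzma among the knockouts. Nothing in the labels says that the 2 libraries of a group came from separate animals, so p-values measure only the spread between these samples.

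RNA of the edited genes did not fall. Dnmt3a (chromosome 12, 3806007 to 3914443) was at 29.1 and 25.9 CPM (counts scaled by library size) in the Rosa KO libraries, 36.0 and 38.7 in Dnmt3a KO, 34.3 and 34.8 in Tet2 KO and 35.2 and 36.5 in Asxl1 KO. In Dnmt3a KO it rose by a log2 change of 0.44 (SE 0.09, adjusted p = 0.00192, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). It also rose in Tet2 KO (0.32, adjusted p = 0.0117) and in Asxl1 KO (0.38, adjusted p = 0.00312). Tet2 (chromosome 3, 133463679 to 133545139) was at 50.1 and 57.8 CPM in Rosa KO, 50.2 and 54.6 in Dnmt3a KO, 53.5 and 48.0 in Tet2 KO and 52.4 and 53.2 in Asxl1 KO. In Tet2 KO it changed by -0.08 (SE 0.09, adjusted p = 0.508). Asxl1 (chromosome 2, 153345829 to 153404007) was at 53.2 and 59.9 CPM in Rosa KO, 61.3 and 58.1 in Dnmt3a KO, 62.5 and 64.2 in Tet2 KO and 54.7 and 58.8 in Asxl1 KO, where it changed by 0.01 (SE 0.07, adjusted p = 0.947). Guide positions are not given, and a 3' tag outside the edited part checks nothing, so these values test neither the edits nor their efficiency.

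T cells made up most of each library, but not all of it. Of the cells that passed the filters, 30.5% and 26.6% in Rosa KO, 21.1% and 20.6% in Dnmt3a KO, 32.7% and 39.2% in Tet2 KO and 25.3% and 23.8% in Asxl1 KO fell in clusters with markers of other spleen cells, mainly B cells and macrophages, although the sort was for CD8+CD90.1+ cells. Many of these droplets held T cell RNA as well: Cd3e was at 806.9 CPM in macrophage cluster 4 (1425 cells) and 558.6 CPM in B cell cluster 5 (1357 cells), against 774.6 CPM in effector-like cluster 0, so they are not plainly other cells. That left 1660 and 1601 P14-like cells in Rosa KO, 2556 and 2073 in Dnmt3a KO, 2369 and 1389 in Tet2 KO and 3173 and 6217 in Asxl1 KO. Trav14-1, the alpha segment of the P14 receptor, had a UMI in 60.8% and 63.4% of P14-like cells in Rosa KO, 54.8% and 56.1% in Dnmt3a KO, 51.1% and 56.2% in Tet2 KO and 46.1% and 37.4% in Asxl1 KO, whose cells held fewer UMIs. B cell droplets also held it, in 34.1% and 33.3% (Rosa KO), 27.9% and 29.4% (Dnmt3a KO), 25.1% and 27.3% (Tet2 KO) and 22.2% and 18.5% (Asxl1 KO), so T cell RNA was present in these droplets.

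Libraries also differed in early-response RNA. Fos and Dusp1, which cells switch on within minutes of stimulation or handling, were nearly absent in both Dnmt3a KO and both Asxl1 KO libraries: Fos was at 3.96 CPM (SD 0.642) in Dnmt3a KO against 89.0 (SD 1.78) in Rosa KO. Cells with little activation-induced RNA were 22.7% and 22.4% of P14-like cells in Rosa KO, 75.5% and 74.4% in Dnmt3a KO, 31.5% and 44.3% in Tet2 KO and 74.98% and 75.4% in Asxl1 KO. The cutoff was the 75th percentile of Dnmt3a KO cells, so the share of that group was fixed by it. Droplets of host cells in the same libraries moved too, with 20 of 28 tested members of the activation-induced list lower in B cells of Dnmt3a KO (median log2 change -1.41) and 21 in those of Asxl1 KO (median -1.35), and none lower in those of Tet2 KO. Groups and libraries cannot be told apart here, so the changes of these genes are given as values of the libraries.

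**Figure D1:**
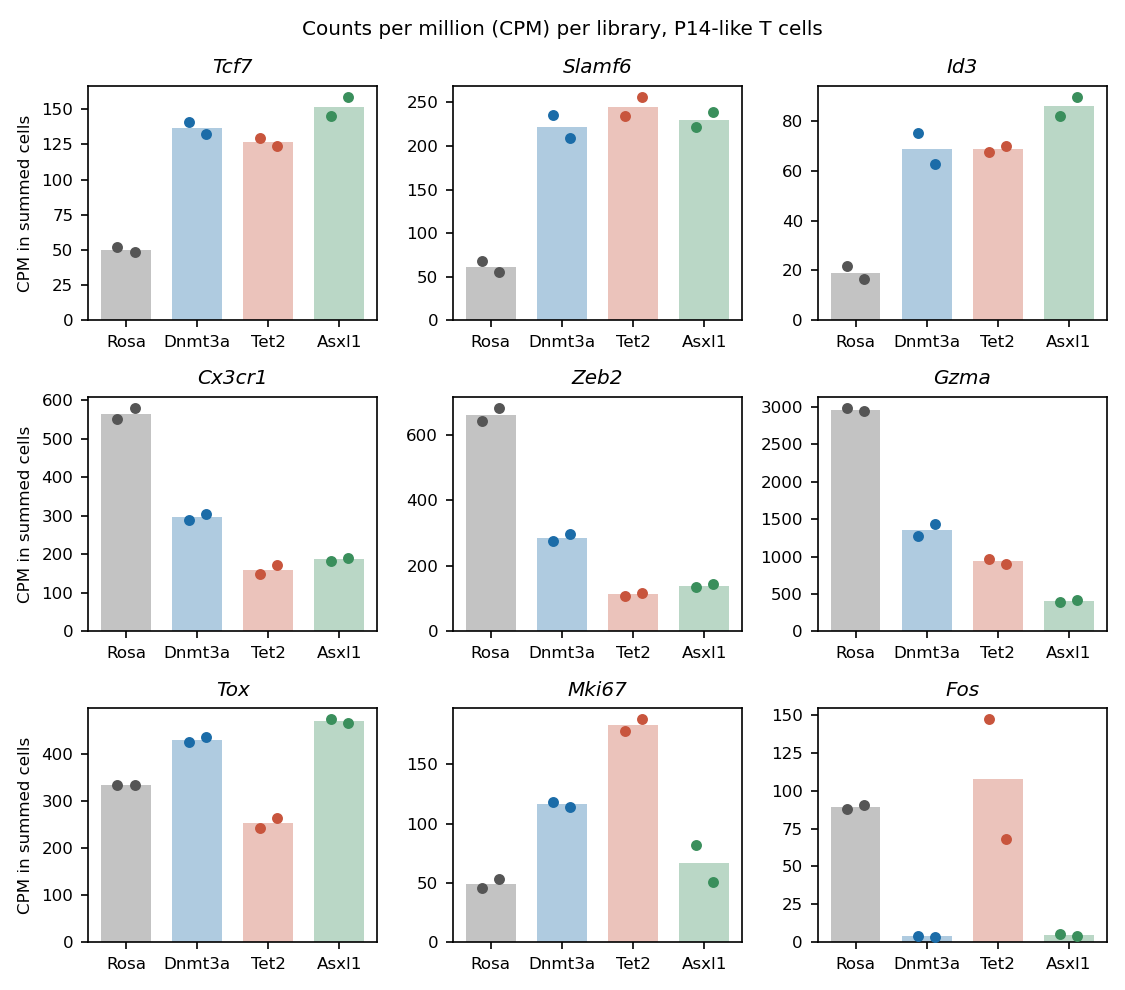
CPM of 9 genes in the P14-like sums of each library. Points are libraries and bars are group means.

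Dnmt3a KO cells carried more RNA of genes that keep T cells in a progenitor state and less of genes of circulating, killing effectors. Interferon-stimulated and cell cycle lists passed camera, but no list passed with an estimated correlation. Cell cycle genes were also higher in B cell droplets, and 1 of 39 G2/M genes was called in activation-low P14-like cells. Early-response RNA fell most of all, and was lower in B cell droplets too, where P14 RNA was not excluded as its source. The inhibitory receptors Pdcd1 and Lag3 were slightly higher.

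Among 24 progenitor-associated genes, 16 were higher and 2 lower in Dnmt3a KO (18 and 2 adjusted over the list alone), with a median log2 change of 0.77 (camera adjusted p = 6.72e-10, and adjusted p = 0.246 with an estimated correlation). Tcf7, the transcription factor that maintains stem-like CD8 T cells, rose by 1.45 (SE 0.07, adjusted p = 1.67e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), from 50.2 CPM (SD 2.27) to 137 CPM (SD 6.11). Slamf6, the surface receptor used to sort these cells, rose by 1.85 (SE 0.09, adjusted p = 1.67e-09), the survival receptor Il7r by 1.66 (SE 0.07, adjusted p = 1.03e-09) and Id3, which restrains effector differentiation, by 1.84 (SE 0.12, adjusted p = 3.30e-08). Tnfsf8, a ligand of the TNF family, rose by 1.53, Tnfrsf4, a costimulatory receptor, by 1.73, Myb, which sustains stem-like exhausted cells, by 1.30 and the chemokine Xcl1, which draws dendritic cells, by 0.97. Bach2, a repressor of effector genes, changed by 0.34 (adjusted p = 0.0538).

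The Cx3cr1 effector list moved the other way, with 0 higher and 19 lower of 22 (the same numbers adjusted over the list alone; median -0.69, camera adjusted p = 8.47e-14, and adjusted p = 0.246 with an estimated correlation). Zeb2, which drives terminal effector differentiation, fell by 1.21 (SE 0.06, adjusted p = 1.67e-09, edgeR quasi-likelihood test, Benjamini-Hochberg), and S1pr5, which lets effectors leave tissue for blood, fell by 1.59 (SE 0.06, adjusted p = 5.02e-10). Cx3cr1, the fractalkine receptor, fell by 0.93 and Klrg1, a marker of terminal effectors, by 1.41. Cytotoxic granule genes were 0 higher and 8 lower of 15 (0 and 9 over the list alone; median -0.29, camera adjusted p = 5.1e-06, and adjusted p = 0.385 with an estimated correlation). Gzma fell by 1.13, Gzmb by 0.83, the death ligand Fasl by 0.76 and the pore protein Prf1 by 0.53. NK receptors were 0 higher and 13 lower of 20 (0 and 15; median -0.88, camera adjusted p = 1.32e-08, and adjusted p = 0.221 with an estimated correlation), led by Klrb1c at -2.14 and Klre1 at -1.36. The NK cell list, which shares members with both, was 2 higher and 8 lower of 15 (2 and 11; median -0.87, camera adjusted p = 0.000328, and adjusted p = 0.246 with an estimated correlation). Chemokine and homing receptors were 4 higher and 13 lower of 22 (4 and 14; median -0.32, camera adjusted p = 0.00301, and adjusted p = 0.246 with an estimated correlation), among them the collagen-binding integrin Itga1 at -1.12.

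Type I interferon genes were 24 higher and 1 lower of 43 in Dnmt3a KO (29 and 2 adjusted over the list alone; median 0.28, camera adjusted p = 1.33e-07, and adjusted p = 0.246 with an estimated correlation), for example Parp14, an ADP-ribosyltransferase, at 0.56 and Ifi27l2a at 0.65. G2/M genes were 32 higher and 0 lower of 39 (34 and 0; median 1.252, camera adjusted p = 9.52e-14, and adjusted p = 0.572 with an estimated correlation), with the topoisomerase Top2a at 0.82, the kinase Plk1 at 1.56, the centromere protein Cenpf at 1.93 and Mki67 at 1.23. S phase genes were 17 higher and 1 lower of 36 (19 and 1; median 0.37, camera adjusted p = 2.22e-06, and adjusted p = 0.548 with an estimated correlation), with the PCNA partner Pclaf at 1.19 and the nucleotide-making subunit Rrm2 at 0.96. In B cells of the same libraries 35 of 39 G2/M genes were higher as well, and among activation-low P14-like cells 1 of 39 was. T cell receptor signalling genes were 7 higher and 0 lower of 23 (9 and 1; median 0.12, camera adjusted p = 0.0135, and adjusted p = 0.246 with an estimated correlation), with the dampening genes Ubash3a at 0.39 and Cd5 at 0.34. The list for CD4 and regulatory T cells was 8 higher and 3 lower of 12 (8 and 3; median 1.10, camera adjusted p = 0.0131, and adjusted p = 0.246 with an estimated correlation). It shares Tnfsf8, Tnfrsf4 and Ikzf2 (0.72) with the progenitor list. Cd4 itself rose by 2.43, from 1.09 and 1.07 CPM in the Rosa KO libraries to 5.29 and 6.47 CPM.

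Exhaustion genes split in Dnmt3a KO: Tox, which fixes the exhausted state, rose by 0.36 (SE 0.05, adjusted p = 0.000164, edgeR quasi-likelihood test, Benjamini-Hochberg), Pdcd1 by 0.45 and Lag3 by 0.30, while the ectoenzyme Entpd1 fell by 0.41 and Cxcr6 by 0.42. Havcr2 changed by -0.16 (adjusted p = 0.108) and Cd101, a mark of terminal exhaustion, by 0.32 (adjusted p = 0.0955). Eomes, a regulator of memory and exhaustion, rose by 0.77, while Tbx21, a driver of effector differentiation, fell by 0.55 and Klf2, which keeps cells circulating, by 0.54. The cytokine Ifng fell by 2.05 and the chemokine Ccl9 by 2.90. Ifng and Klf2 were among the genes correlated with the recently activated markers in Rosa KO cells, so they are not independent of the activation genes. The activation-induced list was 2 higher and 22 lower of 28 (2 and 22; median -1.57, camera adjusted p = 5.56e-11, and adjusted p = 0.572 with an estimated correlation). Fos fell by 4.47, the phosphatase Dusp1 by 4.04, Jun by 2.34, Nr4a2 by 2.03 and the retention marker Cd69 by 1.58. Of the same list, the NF-kappaB brake Tnfaip3 fell by 2.59, the stress phosphatase subunit Ppp1r15a by 2.41 and Fosb by 2.40. Outside the lists, Rgs2, which dampens G protein signals, fell by 2.35, while Ttn (2.28) and Rgs10 (1.75) rose. Rgs2 too was correlated with the recently activated markers.

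In all, 2353 of 11970 genes were called in Dnmt3a KO, 1123 higher and 1230 lower. The DESeq2 Wald test called 1247, sums of equal size 862 and activation-low cells 572. The count fell to 1377 without Rosa KO replicate 1, 1390 without Rosa KO replicate 2, 1262 without Dnmt3a KO replicate 1 and 1359 without Dnmt3a KO replicate 2.

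Lists that did not pass camera in Dnmt3a KO are given as genes higher and lower of those tested, then the same counts adjusted over the list alone, then the camera adjusted p. They were terminal exhaustion (8 and 9 of 24, 9 and 10, 0.899, with a median of 0.0023 and a mean of -0.24) and inhibitory receptors (6 and 4 of 16, 7 and 6, 0.691). Signalling lists were cytokines and chemokines (5 and 7 of 19, 7 and 7, 0.867, median 0.04 and mean -0.10) and common gamma chain receptors (6 and 4 of 18, 7 and 4, 0.561). Others were heat shock (3 and 4 of 14, 4 and 6, 0.857), interferon gamma and antigen presentation (5 and 4 of 31, 7 and 4, 0.295) and glycolysis (6 and 2 of 21, 7 and 2, 0.306). Then came nuclear-encoded oxidative phosphorylation (3 and 17 of 74, 6 and 19, 0.156), mitochondrially encoded genes (3 and 1 of 13, 6 and 4, 0.543, median 0.09 and mean -0.01) and cholesterol and fatty acid synthesis (1 and 1 of 25, 0 and 0, 0.754). Also without a pass were apoptosis (4 and 9 of 24, 5 and 9, 0.463), p53 targets (0 and 4 of 17, 0 and 4, 0.376) and ASXL, BAP1 and PRC1 (2 and 2 of 29, 2 and 2, 0.994). Chromatin and silencing lists were PRC2 (1 and 1 of 12, 1 and 1, 0.475), DNA methylation enzymes (4 and 0 of 18, 4 and 0, 0.228), germline genes silenced by DNA methylation (0 and 0 of 3, 0 and 0, 0.729), imprinted genes (1 and 2 of 11, 1 and 2, 0.982, median 0.07 and mean -0.08) and sex-linked genes (0 and 1 of 5, 0 and 1, 0.729). For other cell types they were B cells (2 and 0 of 19, 1 and 0, 0.396), plasma cells (1 and 2 of 13, 1 and 2, 0.994) and macrophages (2 and 2 of 20, 2 and 2, 0.647). Further ones were neutrophils (1 and 2 of 6, 2 and 4, 0.914), dendritic cells (1 and 1 of 11, 1 and 1, 0.673), erythroid cells (1 and 0 of 6, 1 and 0, 0.914), platelets (0 and 0 of 3, 0 and 0, 0.729) and gamma-delta T cells (2 and 1 of 7, 2 and 2, 0.754). Neither of 2 HOX genes was called, and 1 of 2 stromal genes was higher.

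Tet2 KO cells also had more RNA of progenitor genes and less of effector genes, with Zeb2 and S1pr5 lower than in Dnmt3a KO. Most cell division genes rose as well, and Mki67 was higher than in Dnmt3a KO and in Asxl1 KO by direct test. The cell division lists were not tested between knockouts. Lists of interferon-stimulated, glycolysis and respiration genes passed camera too, but no list passed with an estimated correlation. Tox, which the other knockouts raised, was lower here, as was Entpd1. Early-response genes as a list did not pass, with a median log2 change of -0.05. RNA of B cells and macrophages was higher in the Tet2 KO P14-like sums.

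Of 24 progenitor-associated genes, 18 were higher and 2 lower in Tet2 KO (18 and 2 adjusted over the list alone; median 0.96, camera adjusted p = 3.37e-07, and adjusted p = 0.246 with an estimated correlation). Slamf6 rose by 1.99 (SE 0.09, adjusted p = 3.49e-10, edgeR quasi-likelihood test, Benjamini-Hochberg), from 61.6 CPM (SD 8.51) to 245 CPM (SD 15.4), Tcf7 by 1.34 (SE 0.07, adjusted p = 2.33e-09), Id3 by 1.84 and Il7r by 1.91. Xcl1 rose by 1.21 and Myb by 1.51, and Bach2 changed by 0.10 (adjusted p = 0.584).

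S1pr5, Zeb2, Klrg1, Cx3cr1, Gzma and Prf1 fell further in Tet2 KO than in Dnmt3a KO by direct test, but Gzmb fell less. The Cx3cr1 effector list was 1 higher and 17 lower of 22 (1 and 17; median -0.63, camera adjusted p = 5.21e-10, and adjusted p = 0.246 with an estimated correlation). S1pr5 fell by 3.44 (SE 0.08, adjusted p = 2.06e-13, edgeR quasi-likelihood test, Benjamini-Hochberg), from 166 to 15.4 CPM, Zeb2 by 2.54 (SE 0.06, adjusted p = 3.7e-13), Klrg1 by 2.98, Cx3cr1 by 1.82 and the master regulator Tbx21 by 1.01. NK receptors were 2 higher and 13 lower of 20 (2 and 13; median -1.15, camera adjusted p = 3.58e-05, and adjusted p = 0.246 with an estimated correlation), with Klrb1c at -3.41 and Klre1 at -2.30. The NK cell list was 2 higher and 9 lower of 15 (2 and 9; median -1.08, camera adjusted p = 0.00301, and adjusted p = 0.246 with an estimated correlation). Cytotoxic granule genes were 1 higher and 8 lower of 15 (2 and 9; median -0.32, camera adjusted p = 0.00533, and adjusted p = 0.574 with an estimated correlation). Gzma fell by 1.66, Prf1 by 1.08, Fasl by 0.95, the granzyme B inhibitor Serpinb9 by 0.67 and Gzmb by 0.51. Ccl9 fell by 4.05, Gpr55, a lipid receptor, by 2.78 and Itga1 by 2.07.

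Most cell division genes rose in Tet2 KO. G2/M genes were 37 higher and 0 lower of 39 (38 and 0; median 1.92, camera adjusted p = 5.49e-18, and adjusted p = 0.483 with an estimated correlation). S phase genes were 30 higher and 0 lower of 36 (31 and 0; median 0.82, camera adjusted p = 6.23e-14, and adjusted p = 0.266 with an estimated correlation). Cenpf rose by 2.82, Hmmr by 2.69, the survivin gene Birc5 by 2.56, the cyclin Ccnb2 by 2.48, Ube2c, which helps destroy cyclins, by 2.40, Cdca3 by 2.31, Tpx2, a spindle factor, by 2.24 and Mki67 by 1.89 (SE 0.15, adjusted p = 1.99e-07, edgeR quasi-likelihood test, Benjamini-Hochberg). With proliferating-like cells left out, Mki67 changed by -0.00792. Among S phase genes, Uhrf1, which carries DNA methylation through replication, rose by 1.89, Pclaf by 2.15 and the helicase subunit Mcm3 by 1.02. Host B cells of Tet2 KO had 3 of 39 G2/M genes higher, and 39 of 39 were higher in activation-low P14-like cells.

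Interferon and metabolic lists passed camera as well. The type I interferon list was 31 higher and 0 lower of 43 in Tet2 KO (33 and 0; median 0.42, camera adjusted p = 6.72e-10, and adjusted p = 0.246 with an estimated correlation), with Ifi27l2a at 1.09, the ubiquitin-like Isg15 at 0.87, the virus tether Bst2 at 0.65 and Slfn5 at 1.49. Cxcl10, a chemokine that draws T cells, rose by 2.60 (SE 0.12, adjusted p = 3.81e-10, edgeR quasi-likelihood test, Benjamini-Hochberg). Glycolysis genes were 11 higher and 0 lower of 21 (11 and 1; median 0.35, camera adjusted p = 0.0031, and adjusted p = 0.266 with an estimated correlation), such as Tpi1 at 1.14 and the lactate dehydrogenase Ldha at 0.60. Nuclear-encoded respiratory genes were 32 higher and 8 lower of 74 (34 and 8; median 0.11, camera adjusted p = 0.00412, and adjusted p = 0.66 with an estimated correlation), with the ATP synthase subunit Atp5g3 at 0.46. Mitochondrially encoded genes were 9 higher and 1 lower of 13 (9 and 1; median 0.36, camera adjusted p = 0.00431, and adjusted p = 0.574 with an estimated correlation), with mt-Co3 at 0.58. Lipid synthesis genes were 12 higher and 1 lower of 25 (12 and 1; median 0.36, camera adjusted p = 0.00732, and adjusted p = 0.335 with an estimated correlation), with the cholesterol pathway enzymes Fdps at 0.91 and Sqle at 0.73. B cell genes were 13 higher and 0 lower of 19 (15 and 0; median 1.02, camera adjusted p = 8.47e-05, and adjusted p = 0.574 with an estimated correlation), with Cd79a at 23.7 against 9.02 CPM. Macrophage genes were 14 higher and 1 lower of 20 (15 and 1; median 0.75, camera adjusted p = 0.000411, and adjusted p = 0.413 with an estimated correlation), with the lipid carrier Apoe at 1.31. Cxcl10 belongs to the interferon gamma list, which did not pass.

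Exhaustion genes leaned lower in Tet2 KO without passing as a list: Tox fell by 0.40 (SE 0.05, adjusted p = 4.69e-05, edgeR quasi-likelihood test, Benjamini-Hochberg), Entpd1 by 1.14, Cxcr6 by 0.81 and Havcr2 by 0.27, while Lag3 rose by 0.37. Pdcd1 changed by -0.04 (adjusted p = 0.634), Cd101 by -0.10 (adjusted p = 0.67) and Ifng by -0.40 (adjusted p = 0.189). Eomes rose by 0.82, while Klf2 fell by 0.82 and Nr4a2 by 0.44.

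Tet2 KO had 3705 of 11970 genes called, 1944 higher and 1761 lower. The DESeq2 Wald test called 2136, sums of equal size 1600 and activation-low cells 2159. Without Rosa KO replicate 1 the count was 2453.

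The remaining lists in Tet2 KO, in the same order of values, were terminal exhaustion (2 and 10 of 24, 2 and 10, 0.119), inhibitory receptors (5 and 7 of 16, 5 and 7, 0.379) and cytokines and chemokines (6 and 5 of 19, 6 and 5, 0.754, median 0.12 and mean -0.02). Further signalling lists were homing receptors (7 and 10 of 22, 7 and 10, 0.171) and common gamma chain receptors (4 and 7 of 18, 4 and 7, 0.691, median -0.02 and mean 0.07). Stimulation lists were T cell receptor signalling (5 and 10 of 23, 6 and 11, 0.275), activation-induced genes (3 and 7 of 28, 3 and 7, 0.463) and heat shock (2 and 1 of 14, 2 and 1, 0.837). Others were interferon gamma and antigen presentation (12 and 6 of 31, 12 and 9, 0.268), apoptosis (8 and 5 of 24, 8 and 6, 0.729) and p53 targets (2 and 3 of 17, 2 and 3, 0.709, median -0.03 and mean 0.03). Chromatin lists were ASXL, BAP1 and PRC1 (1 and 6 of 29, 1 and 5, 0.299), PRC2 (4 and 2 of 12, 4 and 2, 0.543) and DNA methylation enzymes (3 and 5 of 18, 3 and 5, 0.676). Silenced and sex-linked lists were germline genes (0 and 0 of 3, 0 and 0, 0.853), imprinted genes (2 and 2 of 11, 2 and 3, 0.352) and sex-linked genes (0 and 2 of 5, 0 and 3, 0.272). For other cell types they were plasma cells (5 and 1 of 13, 5 and 1, 0.376), neutrophils (0 and 2 of 6, 0 and 2, 0.258) and dendritic cells (6 and 1 of 11, 6 and 2, 0.295). Blood and T cell lists were erythroid cells (3 and 0 of 6, 4 and 1, 0.728), platelets (0 and 0 of 3, 0 and 0, 0.709), CD4 T cells (7 and 2 of 12, 7 and 3, 0.225) and gamma-delta T cells (3 and 2 of 7, 3 and 2, 0.475, median 0.41 and mean -0.05). Neither of 2 HOX genes was called, and Pecam1 (1.16) was the higher of 2 stromal genes.

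Asxl1 KO cells combined the rise of progenitor genes with the deepest loss of granzyme RNA, but here too no list passed with an estimated correlation. Zeb2 and S1pr5 fell further than in Dnmt3a KO but less than in Tet2 KO. Unlike in Tet2 KO, Tox and Pdcd1 rose. Of 39 G2/M genes 10 were higher, against 37 in Tet2 KO, while in activation-low cells 0 were higher and 4 lower. As in Dnmt3a KO, early-response RNA was lower in P14-like cells and in B cell droplets.

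In Asxl1 KO, 19 of 24 progenitor-associated genes were higher and 4 lower (20 and 4 adjusted over the list alone; median 0.92, camera adjusted p = 6.2e-07, and adjusted p = 0.246 with an estimated correlation). Id3 rose by 2.16 (SE 0.11, adjusted p = 1.82e-09, edgeR quasi-likelihood test, Benjamini-Hochberg), from 19.13 CPM (SD 3.77) to 85.7 CPM (SD 5.2), Slamf6 by 1.90 (SE 0.09, adjusted p = 3.54e-10), Tcf7 by 1.60 (SE 0.07, adjusted p = 1.64e-10), Myb by 1.54, Eomes by 1.11 and Il7r by 1.11. Xcl1 rose by 1.06 and Bach2 by 0.47, and Bach2 reversed to -0.08 with other cell types kept. The peptide hormone gene Enho (1.79), the neuronal trafficking gene Nsg2 (1.79), Kbtbd11 (1.72) and the mitochondrial gene Chchd10 (1.51) were among the highest.

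Every Cx3cr1 effector gene but 1 was lower in Asxl1 KO: 0 higher and 21 lower of 22 (0 and 21; median -1.03, camera adjusted p = 6.95e-18, and adjusted p = 0.246 with an estimated correlation). Gzma fell by 2.86 (SE 0.07, adjusted p = 1.87e-13, edgeR quasi-likelihood test, Benjamini-Hochberg), from 2962 to 408 CPM, Zeb2 by 2.24 (SE 0.06, adjusted p = 7.13e-13), S1pr5 by 2.59, Klrg1 by 2.25, Cx3cr1 by 1.60, Klf2 by 0.82 and Tbx21 by 0.59. Granule genes were 2 higher and 8 lower of 15 (3 and 9; median -0.23, camera adjusted p = 0.029, and adjusted p = 0.669 with an estimated correlation), with Gzmb at -1.32, Serpinb9 at -0.54 and Fasl at -0.47, and Prf1 fell by only 0.23. NK receptors were 0 higher and 14 lower of 20 (0 and 15; median -1.33, camera adjusted p = 1.21e-09, and adjusted p = 0.221 with an estimated correlation), with Klrb1c at -3.15, Klre1 at -2.41 and Klrc2 at -1.56. The NK cell list was 3 higher and 10 lower of 15 (3 and 10; median -1.09, camera adjusted p = 0.00146, and adjusted p = 0.246 with an estimated correlation). Homing receptors were 5 higher and 14 lower of 22 (5 and 15; median -0.42, camera adjusted p = 0.000828, and adjusted p = 0.246 with an estimated correlation), with the integrins Itga1 at -2.11 and Itgb1 at -0.94. Ccl9 fell by 3.38.

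Inhibitory and exhaustion genes split again in Asxl1 KO: Tox rose by 0.49 (SE 0.05, adjusted p = 5.36e-06, edgeR quasi-likelihood test, Benjamini-Hochberg), Pdcd1 by 0.48 and Lag3 by 0.47, while Entpd1 fell by 0.52, Havcr2 by 0.37 and Cxcr6 by 0.36. Cd101 changed by 0.33 (adjusted p = 0.0653) and Mki67 by 0.41 (adjusted p = 0.0562). Type I interferon genes were 21 higher and 5 lower of 43 (23 and 5; median 0.21, camera adjusted p = 0.00164, and adjusted p = 0.483 with an estimated correlation), with Rnf213 at 0.62, Isg15 at 0.59 and the exonuclease Isg20 at 0.68. G2/M genes were 10 higher and 2 lower of 39 (14 and 2; median 0.39, camera adjusted p = 0.00802, and adjusted p = 0.881 with an estimated correlation), with Cenpf at 1.31 and Nek2 at 1.79 but the kinetochore gene Ndc80 at -0.56. In host B cells of Asxl1 KO 27 of 39 were higher, and in activation-low P14-like cells 0 were higher and 4 lower. The activation-induced list was 1 higher and 22 lower of 28 (1 and 22; median -1.62, camera adjusted p = 5.75e-10, and adjusted p = 0.572 with an estimated correlation). Fos fell by 4.15, Dusp1 by 4.00, Nr4a2 by 2.01 and Cd69 by 1.63, and so did Tnfaip3, by 2.60. Outside it, Rgs2 fell by 2.50 and Ifng by 1.52, though both were among the genes correlated with the recently activated markers in Rosa KO cells. B cell genes were 13 higher and 0 lower of 19 (14 and 0; median 0.63, camera adjusted p = 0.000108, and adjusted p = 0.574 with an estimated correlation), with Cd79a at 21.5 against 9.02 CPM and Cd22 at 1.57.

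Asxl1 KO had 3569 of 11970 genes called, 1730 higher and 1839 lower. The DESeq2 Wald test called 1983, sums of equal size 1975 and activation-low cells 1492. The count was 2205 without Rosa KO replicate 1, 2356 without Rosa KO replicate 2 and 2357 without Asxl1 KO replicate 2.

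The remaining lists in Asxl1 KO, again as higher and lower of tested, the counts over the list alone and the camera adjusted p, were terminal exhaustion (9 and 10 of 24, 10 and 10, 0.572, median 0.17 and mean -0.08) and inhibitory receptors (5 and 6 of 16, 7 and 6, 0.914, median 0.07 and mean -0.13). Signalling lists were cytokines and chemokines (5 and 6 of 19, 6 and 7, 0.909, median 0.10 and mean -0.08), common gamma chain receptors (6 and 4 of 18, 7 and 4, 0.306) and T cell receptor signalling (9 and 3 of 23, 9 and 3, 0.0672). Stress, interferon and cycle lists were heat shock (2 and 5 of 14, 2 and 5, 0.406), interferon gamma and antigen presentation (13 and 6 of 31, 14 and 7, 0.268) and S phase (3 and 7 of 36, 2 and 7, 0.809, median 0.04 and mean -0.04). Metabolic lists were glycolysis (7 and 2 of 21, 7 and 2, 0.256), nuclear-encoded oxidative phosphorylation (9 and 33 of 74, 11 and 33, 0.0556), mitochondrially encoded genes (4 and 5 of 13, 4 and 5, 0.729) and lipid synthesis (2 and 1 of 25, 2 and 1, 0.475). Death and chromatin lists were apoptosis (3 and 9 of 24, 4 and 9, 0.256), p53 targets (1 and 5 of 17, 1 and 5, 0.272), ASXL, BAP1 and PRC1 (2 and 2 of 29, 2 and 2, 0.994) and PRC2 (1 and 0 of 12, 0 and 0, 0.974). Methylation and silencing lists were DNA methylation enzymes (4 and 1 of 18, 4 and 3, 0.729), germline genes (0 and 0 of 3, 0 and 0, 0.526), imprinted genes (3 and 1 of 11, 3 and 1, 0.547) and sex-linked genes (0 and 1 of 5, 0 and 1, 0.627). For other cell types they were plasma cells (5 and 1 of 13, 5 and 1, 0.463), macrophages (2 and 2 of 20, 2 and 2, 0.994), neutrophils (0 and 2 of 6, 0 and 2, 0.451) and dendritic cells (6 and 1 of 11, 6 and 1, 0.185). Blood and T cell lists were erythroid cells (0 and 1 of 6, 0 and 1, 0.729), platelets (0 and 0 of 3, 0 and 0, 0.697), CD4 T cells (6 and 3 of 12, 7 and 3, 0.171) and gamma-delta T cells (1 and 2 of 7, 1 and 3, 0.899, median 0.22 and mean -0.06). Hoxb4 (0.65) was the higher of 2 HOX genes, and 1 of 2 stromal genes was higher.

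**Figure D2:**
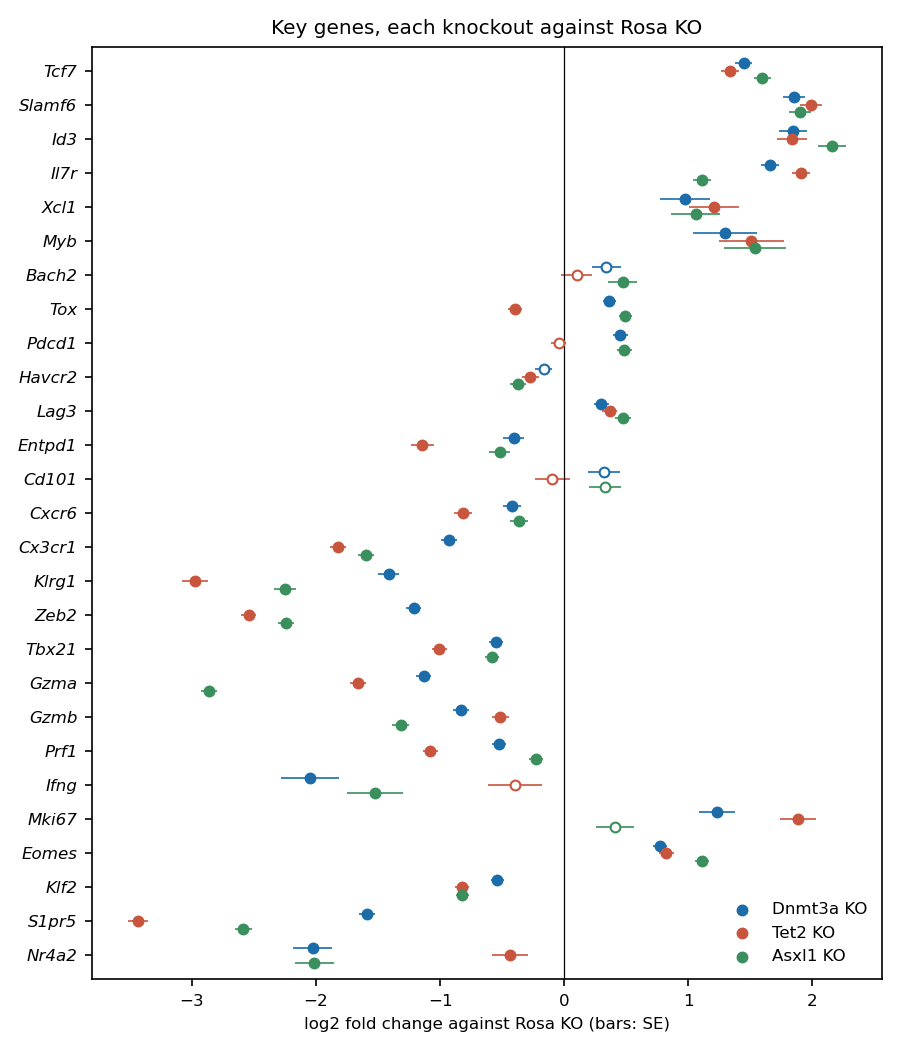
Log2 fold changes with standard errors of 27 key genes in each knockout against Rosa KO. Filled points passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, open points did not.

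**Figure D3:**
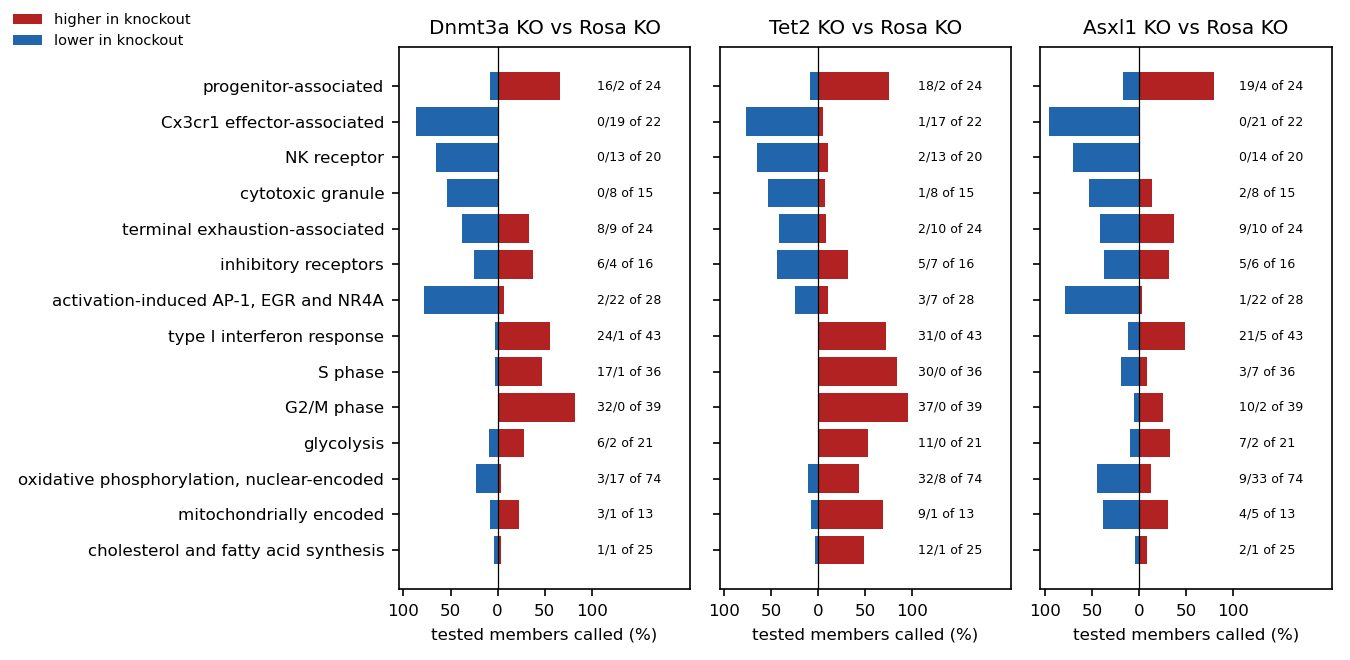
Percent of tested members called higher or lower for 14 of the fixed lists in each knockout against Rosa KO. Text gives the numbers of genes.

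Much of the change was common to the knockouts. Tcf7, Slamf6, Id3, Il7r and Myb rose and Cx3cr1, Zeb2, Klrg1, S1pr5, Gzma and Ccl9 fell in all 3. Genes called in the same direction in all 3 knockouts numbered 491 higher and 638 lower, where chance would give 26.4 and 27.8. Dnmt3a and Tet2 KO shared 1450 calls (727 higher and 723 lower, chance 182 and 181), Dnmt3a and Asxl1 KO 1727 (746 and 981, chance 162 and 189) and Tet2 and Asxl1 KO 1793 (855 and 938, chance 281 and 271), with 47, 9 and 126 genes called in opposite directions. Simulated unchanged groups against the same controls shared at most 3 calls, but such groups give few calls that could be shared, so this is no measure of chance overlap. The chance values take the comparisons as independent, although all use the same 2 Rosa KO libraries. The covariances of log2 changes were 0.191, 0.210 and 0.189 against simulated values of 0.0390, 0.0394 and 0.0393, but with 2 controls the shared libraries cannot be split, so part of the excess may come from them. Correlations were 0.641 and 0.752 for the first 2 pairs, above the simulated 0.498 to 0.576 and 0.543 to 0.628, but 0.578 for Tet2 and Asxl1 KO, within the simulated 0.491 to 0.593. DESeq2 gave 747, 917 and 956 for the pairs. Dnmt3a and Tet2 KO shared 855 and 857 without Rosa KO replicates 1 and 2 and 857 and 910 without Dnmt3a KO replicates 1 and 2. Dnmt3a and Asxl1 KO shared 986, 1018, 964 and 1081 without the same libraries, and Tet2 and Asxl1 KO 1065 and 1143 without Rosa KO replicates 1 and 2. The 1129 genes shared by all 3 fell to 569 with DESeq2, 643 without Rosa KO replicate 1, 655 without Rosa KO replicate 2, 672 without Dnmt3a KO replicate 1 and 743 without Dnmt3a KO replicate 2.

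Direct comparisons between knockouts do not use the Rosa KO libraries as a reference. Tcf7 was higher in Asxl1 KO than in Tet2 KO by 0.26 (adjusted p = 0.00513, edgeR quasi-likelihood test, Benjamini-Hochberg), and neither Tcf7 nor Slamf6 was called between the other pairs. Dnmt3a KO against Tet2 KO was at 0.11 for Tcf7 (adjusted p = 0.233) and -0.14 for Slamf6 (adjusted p = 0.224), and Asxl1 KO against Tet2 KO at -0.09 for Slamf6 (adjusted p = 0.437). Asxl1 KO against Dnmt3a KO gave 1124 calls of 11970 (554 higher and 570 lower). Gzma was lower by a log2 change of -1.73 (SE 0.06, adjusted p = 2.24e-10, edgeR quasi-likelihood test, Benjamini-Hochberg), Zeb2 was at -1.03, S1pr5 at -1.0004, Klrg1 at -0.84, Cx3cr1 at -0.67, Mki67 at -0.82 and the naive and stem cell factor Lef1 at -1.20. By contrast, Enho (1.396), the survival gene Ier3 (1.35) and Eomes (0.34) were higher. Tcf7 differed by 0.15 (adjusted p = 0.131), Slamf6 by 0.05 (adjusted p = 0.742) and Tox by 0.13 (adjusted p = 0.148). Fos and Nr4a2, the early-response genes, differed by 0.32 (adjusted p = 0.748) and 0.01 (adjusted p = 0.976). The count was 392 with DESeq2, of which 151 were higher, 335 in sums of equal size, 551 with other cell types kept, 324 without Dnmt3a KO replicate 1, 284 without Dnmt3a KO replicate 2 and 327 without Asxl1 KO replicate 2.

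Tox was higher in both other knockouts than in Tet2 KO, by 0.89 in Asxl1 KO (SE 0.05, adjusted p = 2.23e-08, edgeR quasi-likelihood test, Benjamini-Hochberg) and by 0.76 in Dnmt3a KO (SE 0.05, adjusted p = 2.54e-07), and so were Pdcd1 (0.53 and 0.50), Entpd1 (0.62 and 0.74), Prf1 (0.85 and 0.55) and Gpr55 (2.85 and 2.62). Mki67 (-1.47 and -0.65) and the stimulation genes Fos (-4.45 and -4.77) and Dusp1 (-4.28 and -4.32) were lower than in Tet2 KO. The effector gene Zeb2 was higher by 1.33 in Dnmt3a KO and by 0.30 in Asxl1 KO, S1pr5 by 1.85 and 0.85 and Klrg1 by 1.56 and 0.73. Gzma was higher by 0.53 in Dnmt3a KO but lower in Asxl1 KO, at -1.20. Asxl1 KO against Tet2 KO gave 3287 calls (1465 higher and 1822 lower), with 1748 by DESeq2, 1152 in sums of equal size, 2182 without proliferating-like cells and 1951 without Asxl1 KO replicate 2. Dnmt3a KO against Tet2 KO gave 2640 (1138 higher and 1502 lower), with 1234 by DESeq2, 981 in sums of equal size, 1269 without Dnmt3a KO replicate 1, 1390 without Dnmt3a KO replicate 2 and 1540 without Tet2 KO replicate 1.

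**Figure D4:**
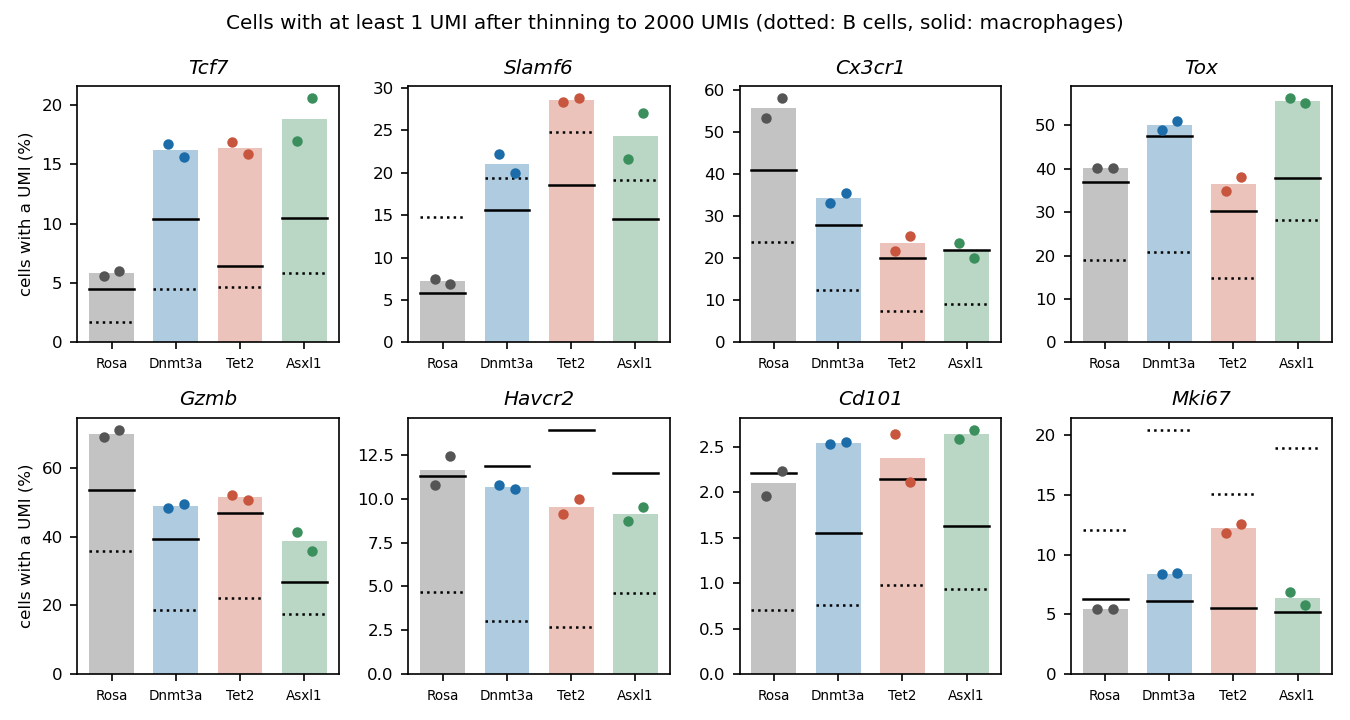
Percent of P14-like cells with a UMI of each of 8 genes after thinning to 2000 UMIs, as group means (bars) and libraries (points). Dotted lines give the share in B cells and solid lines that in macrophages.

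Shares of P14-like cells with a UMI do not use the named states. More knockout cells held Tcf7 and Slamf6 RNA, and fewer held Cx3cr1 and Gzmb. After thinning to 2000 UMIs, Tcf7 was found in 5.84% of Rosa KO cells (SD 0.30), 16.2% of Dnmt3a KO (SD 0.786), 16.4% of Tet2 KO (SD 0.73) and 18.8% of Asxl1 KO cells (SD 2.53), with 1.703%, 4.51%, 4.65% and 5.84% in B cells and 4.52%, 10.4%, 6.44% and 10.5% in macrophages (adjusted p = 0.0435, exact permutation test over 2520 assignments of the 8 libraries, one-sided for a large F). Macrophage shares are no background free of T cells, since most of these droplets lay in cluster 4, with Cd3e at T cell level. Slamf6 was found in 7.22%, 21.1%, 28.5% and 24.4%, with 14.8%, 19.4%, 24.8% and 19.098% in B cells, more than the P14-like share in Rosa KO, and 5.79%, 15.6%, 18.6% and 14.5% in macrophages (adjusted p = 0.0305, exact). Cx3cr1 was found in 55.6%, 34.3%, 23.5% and 21.9% (B cells 23.8%, 12.5%, 7.37% and 9.04%, macrophages 40.95%, 27.97%, 19.985% and 21.98%, adjusted p = 0.0305, exact). Gzmb was found in 70.1%, 49.0%, 51.5% and 38.7% (B cells 35.7%, 18.7%, 22.1% and 17.4%, macrophages 53.5%, 39.4%, 46.8% and 26.8%, adjusted p = 0.0254, exact). Tox was found in 40.2%, 50.003%, 36.5% and 55.7% (B cells 18.9%, 20.7%, 14.8% and 28.2%, macrophages 36.999%, 47.5%, 30.3% and 37.95%, adjusted p = 0.0254, exact). Mki67 was found in 5.45%, 8.39%, 12.2% and 6.33% (B cells 12.1%, 20.5%, 15.1% and 18.9%, macrophages 6.26%, 6.11%, 5.51% and 5.21%, adjusted p = 0.0254, exact). Havcr2 was found in 11.6%, 10.7%, 9.56% and 9.14% (B cells 4.68%, 3.05%, 2.69% and 4.62%, macrophages 11.3%, 11.9%, 13.9% and 11.5%, adjusted p = 0.0435, exact). Cd101 was found in 2.10%, 2.54%, 2.38% and 2.64% (B cells 0.705%, 0.762%, 0.983% and 0.936%, macrophages 2.21%, 1.55%, 2.14% and 1.63%, adjusted p = 0.267, exact). Cells with both Tcf7 and Slamf6, a share added after the data were seen, were 2.61%, 10.96%, 8.82% and 12.1% (B cells 1.08%, 2.36%, 1.87% and 2.89%, macrophages 0.810%, 4.09%, 3.79% and 6.39%, unadjusted p = 0.019, exact).

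Depth matters for these shares. The median P14-like cell held 5283 UMIs in Rosa KO, 4835 in Dnmt3a KO, 4823.5 in Tet2 KO and 2710 in Asxl1 KO, the median B cell 8294.5, 6468, 6764 and 3769 and the median macrophage 4793.5, 4794.5, 4777.5 and 2901. Thinning to 2000 left out 162 (4.97%), 182 (3.93%), 205 (5.46%) and 1877 (19.99%) cells of the groups in that order. Unthinned shares in the same order were 10.4%, 23.5%, 28.9% and 22.04% for Tcf7, 12.6%, 31.8%, 48.5% and 28.5% for Slamf6, 69.3%, 46.0%, 36.8% and 29.0% for Cx3cr1. They were 83.5%, 64.0%, 65.4% and 46.9% for Gzmb, 64.9%, 73.9%, 62.8% and 67.5% for Tox, 11.6%, 15.2%, 19.6% and 8.85% for Mki67, 25.4%, 22.02%, 19.6% and 13.3% for Havcr2 and 5.06%, 6.35%, 5.03% and 4.08% for Cd101. The Tcf7 test missed the threshold at 1500 UMIs (adjusted p = 0.109) and without Rosa KO replicate 2 (0.0508), Dnmt3a KO replicate 1 (0.0762) or 2 (0.0889), Tet2 KO replicate 1 (0.0762) or 2 (0.0653) and Asxl1 KO replicate 2 (0.109), all by the exact permutation test. Slamf6 missed it at 3000 UMIs (0.0762) and without Dnmt3a KO replicate 1 (0.0610) or 2 (0.0762) and Tet2 KO replicate 1 (0.0762) or 2 (0.0635), and Cx3cr1 without Tet2 KO replicate 2 (0.0571), by the same exact test. Tox missed it unthinned (0.390). Havcr2 missed it at 1500 UMIs (0.181) and without 7 of the 8 libraries, that is each but Rosa KO replicate 1: Rosa KO replicate 2 (0.152), Dnmt3a KO replicates 1 (0.152) and 2 (0.141), Tet2 KO replicates 1 (0.0857) and 2 (0.0857) and Asxl1 KO replicates 1 (0.174) and 2 (0.102), exact.

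Clusters named for T cell states were used to look inside the states, not to compare their sizes, because the marker genes that define them were themselves called: 14 of 14 markers for progenitor-like cells, 12 of 13 for Cx3cr1 effector-like, 14 of 15 for terminally exhausted-like, 12 of 12 for proliferating-like, 11 of 12 for interferon-responding-like and 12 of 12 for recently activated-like cells. All 6 classes passed in the main clustering (adjusted p between 0.0381 and 0.0476, exact permutation test on 8 libraries), where progenitor-like cells were 2.17% and 1.69% in Rosa KO, 20.3% and 16.8% in Dnmt3a KO, 9.46% and 13.2% in Tet2 KO and 19.8% and 21.8% in Asxl1 KO. The Tet2 KO shares were 24.5% and 20.5% at Leiden resolution 0.5 and 21.4% and 16.9% when clustered without activation genes. In the main clustering 324 and 77 Tet2 KO cells lay in cluster 17, named recently activated-like with a progenitor score close behind (1.427 and 1.272). The edgeR quasi-likelihood test on cell numbers gave adjusted p between 0.000168 (progenitor-like) and 0.00771 (Benjamini-Hochberg). When cells were clustered without the called genes, no class differed in share (adjusted p between 0.114 for interferon-responding-like and 0.295 for progenitor-like cells, exact permutation test on 8 libraries), and progenitor-like cells were then 14.4% and 12.9% in Rosa KO, 16.7% and 16.5% in Dnmt3a KO, 11.5% and 14.5% in Tet2 KO and 13.9% and 9.95% in Asxl1 KO. That clustering lacks the genes that set the states apart, so it cannot show whether the states changed in size.

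Within the Cx3cr1 effector-like class, Slamf6 rose and Gzma, Zeb2, S1pr5, Klrg1 and Cx3cr1 fell in all 3 knockouts. Unnamed clusters are in no class. Cluster 2, which scored almost alike for recently activated (1.049) and effector cells (0.956), held 624 and 625 cells in Rosa KO, 13 and 14 in Dnmt3a KO, 609 and 191 in Tet2 KO and 8 and 7 in Asxl1 KO. Cluster 10, also unnamed, held 50 and 56, 328 and 267, 120 and 117, and 760 and 1675. The effector-like class thus leaves out different parts of each group. In this class 362 (Dnmt3a KO), 1514 (Tet2 KO) and 764 (Asxl1 KO) of 9638 genes were called. DESeq2 called 103, 710 and 276, and clustering without activation genes left 184 in Tet2 KO. Slamf6 rose by 0.62, 2.74 and 1.53 in the 3 knockouts (adjusted p = 0.0394, 1.92e-19 and 3.06e-09, edgeR quasi-likelihood test, Benjamini-Hochberg), Eomes by 0.81, 1.13 and 1.43 and the cytoskeletal regulator Gas7 by 1.49, 3.16 and 2.50. Tcf7 rose by 1.41 in Tet2 KO and 1.26 in Asxl1 KO, and Il7r by 2.78 and 1.63, but Tcf7 changed by 0.36 in Dnmt3a KO (adjusted p = 0.454). Gzma changed by -1.13, -1.08 and -1.97, Zeb2 by -0.41, -1.76 and -0.74, S1pr5 by -0.72, -2.42 and -0.97, Klrg1 by -0.66, -2.06 and -0.62 and Cx3cr1 itself by -0.25, -1.24 and -0.48, all called. Type I interferon genes were 19 higher and 0 lower of 42 in Tet2 KO, 3 and 0 in Dnmt3a KO and 2 and 2 in Asxl1 KO. The mix of clusters differed as well: of the pair that holds the class, cluster 0 had 76.3% of its cells in Rosa KO, 55.6% in Dnmt3a KO, 22.4% in Tet2 KO and 39.3% in Asxl1 KO. Cluster 0 has 5 effector markers among its top 10 genes, with S1pr5, Klrg1 and Zeb2 in the top 10, and cluster 1 has none, so these changes are not separated from the change in mix.

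Terminally exhausted-like cells changed in granzymes and early-response genes. Gzma rose by 0.31 in Dnmt3a KO and fell by 1.60 in Tet2 KO and by 1.85 in Asxl1 KO (adjusted p = 0.00502, 7.4e-19 and 7.05e-22, edgeR quasi-likelihood test, Benjamini-Hochberg), and Gzmb changed by -0.51, 0.52 and -0.76. Slamf6 rose by 2.56 in Tet2 KO and by 1.14 in Asxl1 KO, Xcl1 by 2.93 in Tet2 KO, and Tox fell by 0.69 in Tet2 KO. Of 27 activation-induced genes, 21 were lower in Dnmt3a KO and 22 in Asxl1 KO, none of them higher, against 3 higher and 1 lower in Tet2 KO. The checkpoint receptor Ctla4 fell by 2.36 in Asxl1 KO. Calls were 200, 280 and 573 of 9131 genes, and 70, 138 and 220 by DESeq2. The class lay in clusters 8 and 9, and cluster 8 had 53.2% of its cells in Rosa KO but 1.98% in Dnmt3a KO and 0.908% in Asxl1 KO.

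Tcf7 and Slamf6, which helped define progenitor-like cells, were not called among them: Tcf7 changed by 0.11, -0.32 and 0.10 (adjusted p = 0.848, 0.348 and 0.833, edgeR quasi-likelihood test, Benjamini-Hochberg) and Slamf6 by 0.25, 0.11 and 0.14 (adjusted p = 0.478, 0.855 and 0.746). Within the class Xcl1 changed by -0.99, -0.95 and -1.07 and the orphan receptor Nr4a2 by -1.81, -0.90 and -2.10, all called. The 63 Rosa KO cells of this class held no UMI of Gzmb, which was at least 4.17-fold higher in Dnmt3a KO, 4.64-fold in Tet2 KO and 4.98-fold in Asxl1 KO (bounds from a floor of 3 counts over the group). Without thinning, 51.8% of Rosa KO B cell droplets held a Gzmb UMI. The Gzmb folds are thus not separated from how cells were placed in the class. In Tet2 KO the receptor Cd160 (2.06) rose, and in Asxl1 KO Prf1 rose by 0.99, Il7r fell by 0.66 and the death receptor Fas by 1.86. Calls were 77, 56 and 129 of 9328 genes in 63, 868, 408 and 1984 cells of Rosa, Dnmt3a, Tet2 and Asxl1 KO. Clustering without activation genes gave 123, 85 and 268.

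Proliferating-like cells of the knockouts had less Xcl1 (-3.28, -3.11 and -2.41), Gzma (-1.18, -0.74 and -1.92) and Zeb2 (-0.78, -1.64 and -1.86) and more of the mitotic kinase Nek2 (1.92, 1.59 and 2.30), with 55, 104 and 112 of 8113 genes called by edgeR's quasi-likelihood test. The antiviral Rsad2, with no UMI in Rosa KO, was at least 4.86-fold higher in Dnmt3a KO and 4.72-fold in Tet2 KO. In interferon-responding-like cells Slamf6 rose by 1.58, 1.34 and 1.55, Cxcl10 by 1.30 in Tet2 KO, and Gzma fell by 1.42 in Tet2 KO and by 3.09 in Asxl1 KO, with 55, 54 and 119 of 6455 genes called.

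Counts within classes depended on single libraries and on the clustering. In effector-like cells they were, for Dnmt3a KO, 141 and 228 without Rosa KO replicates 1 and 2 and 165 and 162 without Dnmt3a KO replicates 1 and 2, for Tet2 KO 951 without Rosa KO replicate 1 and 677 without Tet2 KO replicate 1. For Asxl1 KO they were 390 and 491 without Rosa KO replicates 1 and 2 and 505 and 404 without Asxl1 KO replicates 1 and 2. In terminally exhausted-like cells they were, for Dnmt3a KO, 125 without Rosa KO replicate 1 and 103 and 114 without Dnmt3a KO replicates 1 and 2, for Tet2 KO 158 without Rosa KO replicate 1 and 126 without Tet2 KO replicate 1. For Asxl1 KO they were 288 without Rosa KO replicate 1 and 230 without Asxl1 KO replicate 2. In progenitor-like cells they were 18 without Rosa KO replicate 1 and 42 without Dnmt3a KO replicate 2 for Dnmt3a KO, 23 without Rosa KO replicate 1 and 25 without Tet2 KO replicate 1 for Tet2 KO, and 30 without Rosa KO replicate 1 and 67 without Asxl1 KO replicate 2 for Asxl1 KO. In interferon-responding-like cells they were 31 without Rosa KO replicate 1 and 31 without Tet2 KO replicate 2 for Tet2 KO, and 62 without Rosa KO replicate 1 and 67 without Asxl1 KO replicate 2 for Asxl1 KO. In proliferating-like cells they were, for Dnmt3a KO, 35 and 175 without Rosa KO replicates 1 and 2 and 18 and 25 without Dnmt3a KO replicates 1 and 2, for Tet2 KO 65 and 223 without Rosa KO replicates 1 and 2 and 25 and 59 without Tet2 KO replicates 1 and 2. For Asxl1 KO they were 60 and 194 without Rosa KO replicates 1 and 2, 71 without Dnmt3a KO replicate 2 and 35 and 34 without Asxl1 KO replicates 1 and 2.

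Changes in progenitor-like cells were also set against those in the other P14-like cells. The clusters were formed on genes that include called progenitor and effector markers, which limits how far these can vary within the class. The other cells differ in their mix of states, and the Rosa KO side rests on 36 and 27 cells, so a difference here does not show an effect specific to progenitor-like cells. It was 1.46, 2.38 and 2.24 for Zeb2 in Dnmt3a, Tet2 and Asxl1 KO (adjusted p = 0.0383, 1.98e-05 and 1.93e-06, edgeR quasi-likelihood interaction test, Benjamini-Hochberg), and 3.23 in Tet2 KO and 2.12 in Asxl1 KO for Cx3cr1. In Dnmt3a KO Cx3cr1 differed by 1.29 (adjusted p = 0.432), Gzma was called only in Asxl1 KO (1.52), and Klrg1 and S1pr5 in none. In Tet2 KO the differences were -1.86 for Slamf6, -1.54 for Tcf7, -2.01 for Il7r and -2.20 for Xcl1, genes that mark the cluster itself. The other cells of Tet2 KO include 401 in cluster 17, with Il7r and Xcl1 among its top 10 genes, against 83 in Rosa KO. In Dnmt3a KO none of these 4 was called (Tcf7 0.47, adjusted p = 0.0982), and in Asxl1 KO only Slamf6 was, at -0.49 (Tcf7 0.38, adjusted p = 0.242). Klf2 differed by 0.56, 0.75 and 0.93 in the 3 knockouts. In all, 98, 215 and 145 of 11583 genes differed, and 168, 477 and 358 when cells were clustered without activation genes.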

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

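The comparison between progenitor-like and other P14-like cells was planned, while every test in host cells and every test of an explanation in this part was chosen only after the results were seen.

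Some effects differed between groups of cells. The change in progenitor-like cells differed from that in the other P14-like cells for 98 genes in Dnmt3a KO, 215 in Tet2 KO and 145 in Asxl1 KO (edgeR quasi-likelihood interaction test, Benjamini-Hochberg). These counts do not show an effect specific to the class, because the clusters were formed on genes that include called markers and the Rosa KO side rests on 36 and 27 cells. Type I interferon genes rose more in P14-like cells than in host B cells of the same libraries, by a test of the difference, for 15 genes in Dnmt3a KO, 7 in Tet2 KO and 14 in Asxl1 KO of 43. G2/M genes rose more in P14-like than in host B cells for 36 of 39 genes in Tet2 KO, against 0 in Dnmt3a KO and 0 in Asxl1 KO. Those with the opposite difference were 0, 2 and 4 in the same order. By the same test of the difference, log2 changes against Rosa KO of some activation genes were lower in P14-like than in host B cells. These genes numbered 9 of 28 in Dnmt3a KO, 10 in Tet2 KO and 9 in Asxl1 KO, with 0, 0 and 1 the other way (median differences -0.40, -0.23 and -0.35). In host B cells, which the planned comparisons do not use, 20 activation genes were lower in Dnmt3a KO and 21 in Asxl1 KO, and 35 G2/M genes were higher in Dnmt3a KO and 27 in Asxl1 KO.

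Activation-induced genes such as Fos and Nr4a2 were lower in the Dnmt3a KO and Asxl1 KO libraries, in P14-like cells and in host CD4 T cells. Host CD4 T cell droplets held at most 15.99% of the receptor RNA of P14-like cells. At that share, changes lay below the lowest that P14 RNA could give each gene, by a median of -0.76 in Dnmt3a KO and -0.37 in Asxl1 KO. These sums held only 21 and 26 cells in Rosa KO, 27 and 14 in Dnmt3a KO and 30 and 53 in Asxl1 KO. Of the 41 such Dnmt3a KO cells, 2 held a Trav14-1 UMI, so the share is loosely known and P14 RNA is not excluded there. In B cell droplets, with up to 41.9%, changes lay above that bound (medians 0.46 and 0.62), so P14 RNA there stays open. The list's median in host CD4 T cells was -1.36 in Dnmt3a KO and -0.68 in Asxl1 KO. This argues against an effect of the edit confined to the edited cells only as far as P14 RNA can be set aside in these few cells. A difference between libraries that reached these host cells too would also give such medians. Whether it came from tissue handling, from the recipients or from edited cells acting on their hosts stays open and untested, because groups and libraries coincide, and so does an added effect in the edited cells.

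Progenitor-associated genes such as Tcf7 and Slamf6 were higher and effector-associated genes such as Zeb2 and Gzma lower in all 3 knockouts. The shift in activation genes is argued against as the whole account. Among activation-low cells the progenitor list's median kept at least 0.691 of its value, with a smallest median of 0.66. Effector list medians there were -0.52, -0.64 and -0.91 in Dnmt3a, Tet2 and Asxl1 KO. In Tet2 KO the activation list's median was -0.05 over all cells, against 0.96 for the progenitor list. Activation-low cells kept part of the shift in Dnmt3a KO (median -0.31) and Asxl1 KO (-0.43), so a part played by it there is not excluded. Host T cells as most of the progenitor-like cells are argued against. At least 38.4% of these cells held a Trav14-1 UMI in each knockout library, 0.806 or more of the share in the other P14-like cells. A smaller host part is not excluded. B cell droplets of the knockouts held such a UMI in 18.5% to 29.4%. In Tet2 KO, Trav14-1 was at 125 and 127 CPM in progenitor-like cells against 205 and 195 in the others. Cell number and depth are argued against by sums of equal size, where list medians kept at least 0.939 of their value and the smallest progenitor median was 0.81. A difference between recipients or batches was not tested and stays open, since no label separates it from the groups.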

How the results depend on the processing

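The tests with activation-low cells only, with clustering without activation genes and with the highest Scrublet scores removed were chosen after the data were seen, and the others in this part were planned. For every change of a count given here the cause was not tested, except that fewer libraries, cells or UMIs test with less power.

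Named genes against Rosa KO mostly kept their side of the threshold: of 121, all 121 with a replicate block in the model and with doublets kept, 120 with RLE size factors, 119 with only the 4 libraries compared, 119 with a stricter cell filter, 119 with the highest Scrublet scores removed, 118 with no filter on low counts, 116 with DESeq2, 115 in sums of equal size, 115 with other cell types kept, 111 without proliferating-like cells and 104 in activation-low cells. The replicate block gave 2283, 3568 and 3460 calls for Dnmt3a, Tet2 and Asxl1 KO against Rosa KO, and differences between replicates correlated between groups at -0.0772 to 0.0817. Leaving out 1 library kept 950 gene values, with 8 stronger and 10 weaker. Reversed were Bach2 in Asxl1 KO (-0.0817) with other cell types kept, Mki67 in Tet2 KO without proliferating-like cells (-0.00792) and the unthinned share of cells with Mki67 in Asxl1 KO against Rosa KO (-2.76 points).

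Counts of called genes, for Dnmt3a, Tet2 and Asxl1 KO against Rosa KO and then Asxl1 against Dnmt3a, Asxl1 against Tet2 and Dnmt3a against Tet2 KO, were 1247, 2136, 1983, 392, 1748 and 1234 with DESeq2 and 862, 1600, 1975, 335, 1152 and 981 in sums of equal size. Activation-low cells gave 572, 2159 and 1492 against Rosa KO. Asxl1 against Dnmt3a KO gave 551 with other cell types kept, and Asxl1 against Tet2 KO 2182 without proliferating-like cells. Leaving out 1 library, which leaves a lone sample assumed to vary like the other groups, gave 1262 to 2739, 2453 to 3689, 2205 to 3970, 284 to 1628, 1951 to 3201 and 1269 to 2640 in that order. Shared calls were 747 (Dnmt3a and Tet2), 917 (Dnmt3a and Asxl1), 956 (Tet2 and Asxl1) and 569 (all 3) with DESeq2, and 855 to 1472, 964 to 2004, 1065 to 1752 and 643 to 1153 with 1 library left out. List tests fell from 12, 14 and 10 passing to 0, 0 and 0 with an estimated correlation, while fry passed 15, 21 and 13.

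Class shares passed in the main clustering (adjusted p = 0.0381 for progenitor-like, proliferating-like and recently activated-like, 0.0429 for terminally exhausted-like, 0.0457 for interferon-responding-like and 0.0476 for effector-like cells, exact permutation test, smallest possible p 0.00952). They missed the threshold at Leiden resolution 0.5 for interferon-responding-like (adjusted p = 0.0571) and progenitor-like cells (0.0952), with doublets kept for interferon-responding-like cells (0.0857), and for progenitor-like cells clustered without activation genes (0.0667). Keeping the doublets, 0 to 11 barcodes per library, also redrew classes. Recently activated-like cells went from 6.93% and 6.68% to 48.0% and 49.3% in Rosa KO, and from 16.3% and 8.50% to 41.7% and 22.6% in Tet2 KO. Effector-like cells of Tet2 KO went from 14.1% and 20.4% to 2.77% and 6.62%, while progenitor-like cells there were at 9.61% and 12.3%. Within-class tests were not repeated with these classes. Clustered without called genes, effector-like and proliferating-like cells were at 0.229, interferon-responding-like at 0.114 and progenitor-like, recently activated-like and terminally exhausted-like at 0.295. With 1 library left out, the range was 0.0286 to 0.0952 for recently activated-like cells and 0.0229 to 0.0857 for each of the other classes. Shares of cells with a UMI (exact, same test) missed it for Tcf7 (0.109) and Havcr2 (0.181) at 1500 UMIs, Slamf6 (0.0762) at 3000 and Tox (0.390) unthinned. With 1 library left out they ranged from 0.0254 to 0.109 (Tcf7), 0.0190 to 0.0762 (Slamf6), 0.0254 to 0.0571 (Cx3cr1) and 0.0254 to 0.174 (Havcr2). Differences of shares moved by more than 1 SD in 19 of 24 cases at 1500 and 19 at 3000 UMIs.

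Within classes, for Dnmt3a, Tet2 and Asxl1 KO, DESeq2 called 103, 710 and 276 genes in effector-like cells, 28, 56 and 60 in proliferating-like and 70, 138 and 220 in terminally exhausted-like cells, and 33 (Dnmt3a KO) and 64 (Asxl1 KO) in interferon-responding-like cells. Classes carried from Rosa KO cells gave 1409 in effector-like cells of Asxl1 KO and 96 and 128 in interferon-responding-like cells of Dnmt3a and Tet2 KO. Clustering without activation genes gave 184 in effector-like cells of Tet2 KO, 84 in interferon-responding-like and 83 in proliferating-like cells of Dnmt3a KO, 123, 85 and 268 in progenitor-like cells, and 168, 477 and 358 interactions. With 1 library left out, calls ranged over 141 to 448, 677 to 1526 and 390 to 884 in effector-like cells, 31 to 76 (Tet2 KO) and 62 to 140 (Asxl1 KO) in interferon-responding-like, 18 to 81, 23 to 81 and 30 to 130 in progenitor-like, 18 to 175, 25 to 223 and 34 to 194 in proliferating-like and 103 to 279, 126 to 309 and 230 to 685 in terminally exhausted-like cells.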

Other observations

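Every test in this part was chosen only after the results were seen.

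2 imprinted genes, Kcnq1ot1 and Impact, were called in all 3 knockouts, while the list of imprinted genes did not pass. Kcnq1ot1, the long noncoding RNA that silences genes on the paternal chromosome 7, rose by a log2 change of 0.70 in Dnmt3a KO, 0.48 in Tet2 KO and 0.80 in Asxl1 KO (adjusted p = 3.57e-06, 7.92e-05 and 4.92e-07, edgeR quasi-likelihood test, Benjamini-Hochberg). Impact, a translation regulator expressed from the paternal copy, fell by 0.76, 0.51 and 0.85 (adjusted p = 0.000786, 0.00963 and 0.000175). Both were picked after their values were seen, and allele of origin cannot be read from these counts.

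Cd4 RNA was higher in Dnmt3a KO, in 97 of 4629 P14-like cells, or 1.88% and 2.36% of cells per library against 0.301% and 0.2498% in Rosa KO. Cd4 was chosen after its values were seen. Host CD4 T cells among them are argued against, since 63.9% (exact interval 53.5 to 73.4) held a Trav14-1 UMI, against 4.88% in the CD4 T cell cluster, and 81.4% held a Cd8a UMI. Doublets are argued against by a median UMI count of 5578, 1.16 times that of the other cells. For free Cd4 RNA, the share of B cell droplets with Cd4 was at most 0.467 of that in P14-like cells, just below the bound of 0.5. That share was 0.256% of 391 and 1.10% of 272 droplets in the Dnmt3a KO libraries. So few droplets with Cd4 cannot exclude free RNA. DNA methylation was not measured here, so no mechanism was tested.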
